A study of Homo sapiens with 16 samples.

How the data were processed

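JUN, a subunit of the AP-1 transcription factor, was profiled by CUT&RUN, in which an antibody directs a nuclease to cut out the DNA bound by a protein so that the released fragments can be sequenced. Per the labels, human primary CD4+ memory T cells were stimulated through CD3 and CD28 with TGF-beta at 2 ng/mL for 72 hours, with either CH-223191 at 10 µM, an inhibitor of the aryl hydrocarbon receptor (AHR), or TCDD at 3 nM, its agonist. The labels list 16 libraries, of which 8 were made with the JUN antibody, 4 per treatment. The 8 libraries made with control IgG were not used here, and neither were untreated or vehicle-treated cells, so background binding and the direction of change from rest were not analysed here.

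Per the submitters' processing notes, the tools used were FastQC, Bowtie2, SAMtools, Picard, SEACR, bedtools, ChIPseeker, DiffBind, DESeq2 and HOMER, with the GRCh38 (hg38) build. Their versions, order and settings are not given in the sources used here. The deposited table held a signal value per library for 10948 regions, each 401 bases wide. Every value was a whole number of reads multiplied by 1 factor per library (100% of values whole within 0.01 of a read), and each of the 8 columns summed to 405905, so the deposited signal was scaled to equal reads within these regions. A rise or fall at a region is therefore relative to the other regions of the same library. Division by the factor recovered 187604 to 682099 reads within the regions per library, with a median of 13 to 52 reads per region, and the lowest regions rest on few reads.

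The authors also deposited 1 peak list per library, with the total and the highest coverage signal of each peak in a scaled unit. All highest signals of a list were whole multiples of 1 step. The inverse of that step was taken as the number of fragments in the library (5.67 to 11.6 M). This total is inferred from the values, no source states it, and each result that uses it says so.

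Each region was assigned to the nearest protein-coding gene within 100 kb, by distance to the gene body, with the GRCh38.p14 gene table. That table gives no strand, so transcription starts could not be used as planned. In place of promoters, gene ends were defined as regions within 1 kb of either end of a protein-coding gene. Of the regions, 10342 (94.5%) were assigned, to 6152 genes. The classes held 3395 gene-end, 4591 gene-body and 2962 intergenic regions. Assignment by distance does not show which gene a region acts on. No genome sequence was used here, so the planned DNA motif sets and the correction for GC content were not run.

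The difference per region was tested with limma 3.58.1 (variance trend, robust) on log2(deposited signal + 1), TCDD against AHR inhibitor, two-sided, with Benjamini-Hochberg adjustment over all 10948 regions, a threshold of 0.05 and no filter. A log2 fold on this scale is a difference between means of log values, and at low regions it can lie below or above the log2 ratio of the group means. The main fit had no block, and the fit with the replicate number as a block was set beforehand as a second fit. Same-numbered libraries shared a code in the labels, and their deviations from the group means correlated across regions at 0.35, 0.18, 0.27 and 0.28, against -0.19 to 0.05 for the other combinations. The numbers were therefore treated as pairing the libraries, and blocked values are given where they change a call. The labels do not say what the code marks, so p-values measure the spread between these libraries, which may be partly technical. The names of the deposited lists gave replicate 1 of both groups another run code than replicates 2 to 4, so this batch was balanced between groups.

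The 15 gene lists (227 genes) and the region classes were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and the lists also with fry. Group means of single values were compared by exact two-sided permutation over the 70 assignments of labels, whose smallest p is 0.0286. These permutations take no account of the pairs. An exact sign-flip test of the 4 pairs cannot go below 0.125, so it cannot reach 0.05, and is given beside them for the main measures. Peak lists were compared with bedtools 2.31.1, with at least 1 shared base after merging. Within each group, no pair of libraries agreed within sampling noise (chi-square per degree of freedom 2.13 to 3.97), so each counted as 1 replicate.

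Before the data were examined, the gene lists, tests, other settings and a rule for named regions were fixed. The rule took up to 10 regions in each direction that passed and moved alike in all 4 pairs, 1 per gene, filled by the lowest unadjusted p where fewer passed. It added the highest region of each of CXCL13, IL22, CYP1A1, CYP1B1, AHRR, TIPARP, MAF, PDCD1, BCL6, IL21, ICOS, SOX4, JUN, BATF and AHR, and the 2 regions with the lowest p in each list. These settings covered the block, the pseudocount (0.5 and 5), low regions, scaling, the variance model, leaving out libraries, assignment and class widths, peak height and overlap. Count tests on the recovered reads with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom, thinning to 187604 reads per library, scaling to inferred totals, lists of equal length and a peak height in fragments were added after seeing the data.

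On data simulated for this comparison over 10948 regions, limma without the block recovered 11 of 100 regions changed 2-fold and 84 of 100 changed 4-fold, with 0 false calls. With the block it recovered 56 and 95, with 5 false calls among 156. Each simulated pair took its levels from the real means of that pair, with the same assumed dispersion for all regions. The simulated data thus follow the blocked model by design, and their false calls do not measure those among the real blocked calls.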

Results

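JUN occupancy was measured in 8 CUT&RUN libraries from human primary CD4+ memory T cells that had been activated with TGF-beta for 72 hours, 4 with the AHR inhibitor CH-223191 and 4 with the AHR agonist TCDD. AHR is a transcription factor activated by small ligands. The series title places the comparison in a study of AHR and JUN in T cells that produce CXCL13, a chemokine that attracts B cells, in lupus. The comparison asks where JUN binding differs when AHR is activated rather than blocked. Recovered reads within the 10948 regions numbered 258489 ± 49748 (SD, n = 4) with the inhibitor and 553321 ± 98667 with TCDD.

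More of the JUN signal lay within peaks and regions in the TCDD libraries. Reads within the regions were 2.14 times as many as with the inhibitor, higher in 4 of 4 pairs (exact permutation p = 0.0286, the smallest possible). As a share of the fragments inferred from the peak lists, they were 3.18% ± 1.06 (SD, n = 4) with the inhibitor and 6.49% ± 0.36 with TCDD (exact permutation p = 0.0286, 4 of 4 pairs). Of the regions, 1925 had a peak in no inhibitor list and 187 in no TCDD list, so counting reads within this set can favour TCDD. The inferred library totals differed by a ratio of 0.99 (exact permutation p = 0.971). Peaks covered 11.3 ± 3.70 Mb with the inhibitor and 21.6 ± 3.06 Mb with TCDD (SD, n = 4; exact permutation p = 0.0286, 0.0571 after adjustment over 4 measures). Total signal within peaks was 2.56 times as high, over that longer covered length (exact permutation p = 0.0286, adjusted 0.0571), and signal per covered kb was 1.42 times as high (exact permutation p = 0.0857). Peaks numbered 7153 ± 2634 and 10169 ± 1261 (SD, n = 4; exact permutation p = 0.0571, adjusted 0.0762), and the median width was 1548 ± 410 bases against 1908 ± 117 (exact permutation p = 0.143). None of these 4 peak measures passed 0.05 after adjustment. In the exact sign-flip test of the pairs, reads, their share, covered length, total signal and peak number had the smallest possible p. That p lies above 0.05, and median width and signal per covered kb had a larger one. With a stricter peak height, above the median of all libraries' peaks, the ratios of TCDD to inhibitor for peak number, covered length and total signal were 2.83, 3.77 and 4.03, and with at least 15 fragments at the highest point 3.598, 4.46 and 4.88 (adjusted p = 0.0381 for each).

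**Figure D1:**
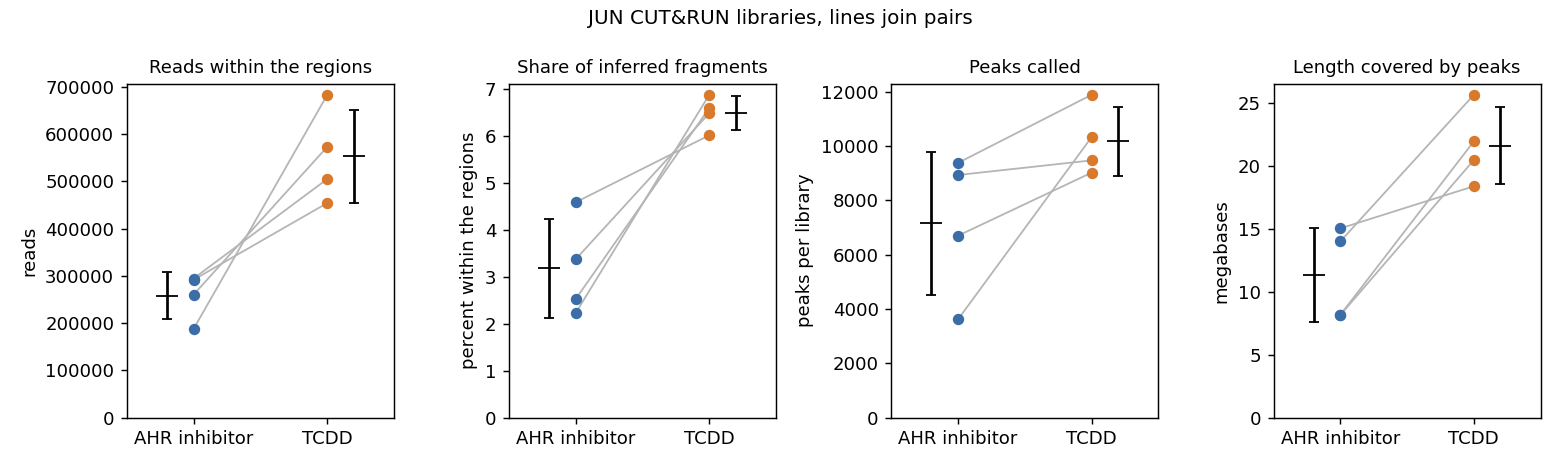
Reads within the regions, the percent of inferred fragments within them, peaks per library and megabases covered by peaks, with 1 point per library, grey lines joining pairs, and the mean and SD of 4 libraries in black. The 4 TCDD libraries held 453900 to 682099 reads within the regions and the 4 inhibitor libraries 187604 to 294404.

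Peaks found with only 1 treatment were mostly those of TCDD. Of 18048 merged peak regions, 771 were called in at least 3 TCDD libraries and in 0 inhibitor libraries, 31 showed the reverse, and 2097 were called in all 8. The TCDD lists overlapped one another with a median Jaccard index of 0.45, against 0.26 among inhibitor lists. Between the groups the median was 0.31, for same-numbered and for other libraries alike, so inhibitor lists overlapped TCDD lists more than one another. The index also depends on the length covered by peaks, which was shorter with the inhibitor. The counts for TCDD and inhibitor alone were 371 and 27 without pair 4, and the 31 became 10, 0 and 10 without pairs 1, 2 and 3. With the stricter height they were 1369 and 4, with 445 called in all 8, and with every list shortened to its 3615 highest peaks 104 and 65, with 1120 in all 8.

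The 2 largest log2 folds of all regions lay on chromosome 3 between LEKR1 and TIPARP, a gene for an ADP-ribosyltransferase induced by AHR. In this interval, 9909 to 55680 bases from LEKR1 and 63503 to 109274 bases from TIPARP, 4 regions within the long noncoding RNA gene LINC00886 were higher with TCDD in 4 of 4 pairs. At 156812691 to 156813091 the signal was 2.28 ± 3.28 (SD, n = 4) with the inhibitor and 33.5 ± 12.7 with TCDD, a log2 fold of 3.86 (2.44 with pseudocount 5). At 156770273 to 156770673 it was 3.55 ± 2.63 and 33.9 ± 14.6, a log2 fold of 3.17 (2.18 with pseudocount 5). The regions at 156788311 and 156816044 had log2 folds of 1.504 and 1.85. With the pairs as a block, limma adjusted p was 3.3e-05, 1.4e-04, 0.026 and 0.0077 at these 4 regions in the order named, and 0.087, 0.13, 0.33 and 0.18 without the block. On the recovered reads without the block, edgeR adjusted p was 0.0093 for each of the first 2 regions named, its only calls, and DESeq2 adjusted p was 0.0010 for each of these and 0.0372 at 156816044. With the block, DESeq2 called only 2 regions higher among all 10948. No inhibitor list had a peak at these 4 regions, and 3 or 4 TCDD lists did, but the lists come from the same libraries as the signal. The highest region inside TIPARP itself, at 156686302, held 6.21 ± 3.83 and 6.62 ± 7.22 (SD, n = 4; log2 fold -0.24), and the other region inside it had a log2 fold of -0.55. LEKR1 is named by the rule, and the other 3 regions of the interval were singled out after their values were seen.

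**Figure D2:**
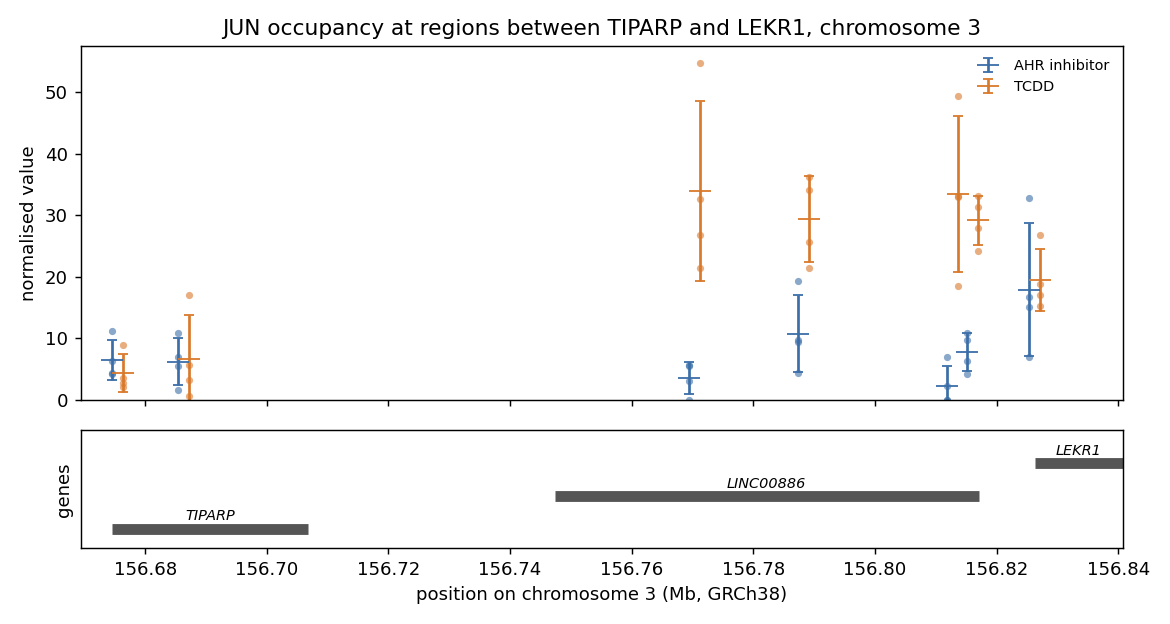
Normalised JUN signal at regions between TIPARP and LEKR1 by position on chromosome 3 (Mb, GRCh38), with 1 point per library, bars for the mean and SD of 4 libraries, and gene extents below. At the 4 regions within LINC00886 TCDD means were 29.1 to 33.9 and inhibitor means 2.28 to 10.7.

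Of the 23 regions assigned to AHR targets, 2 were higher with the pairs as a block and 0 without it, against 81 and 0 of all 10948 regions. A region inside AHRR, the gene for the repressor of AHR, at chromosome 5, 379242 to 379642, held 7.96 ± 2.93 (SD, n = 4) and 27.5 ± 9.68 (log2 fold 1.67, blocked limma adjusted p = 0.019, 0.24 without the block). A region 16398 bases from IL22, a cytokine gene, at chromosome 12, 68270002 to 68270402, held 3.54 ± 3.45 and 17.0 ± 10.4 (SD, n = 4; log2 fold 2.17, blocked limma adjusted p = 0.046, 0.40 without the block). Both were higher in 4 of 4 pairs.

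Across all 10948 regions, limma without the block called 0 regions at 0.05 (862 at an unadjusted p under 0.05, smallest adjusted p 0.087), while on the recovered reads edgeR called 2 higher, and DESeq2 called 10 higher and 5 lower. With the pairs as a block, limma called 81 regions higher and 27 lower with TCDD. All 4 pairs moved alike at 79 of the 81 and at 27 of the 27, which the blocked fit selects for. The median log2 fold was 1.30 (0.60 to 3.86) for the higher and -0.73 (-1.38 to -0.42) for the lower regions, against 0.05 for all regions. Of the 81, 45 had a peak in no inhibitor list, as did 17.6% of all regions, and 15 of the 27 had a peak in all 8 lists, as did 1924 of the 10948. The lists come from the same libraries as the signal, so missing inhibitor peaks at the 81 partly follow from their selection. The median signal was 29.4 at the higher, 97.2 at the lower and 31.5 at all regions. The blocked counts were 109 and 65 with edgeR, 67 and 82 with limma-voom, 2 and 3 with DESeq2, 0 and 0 without the variance trend, and 10 and 3 without pair 2, 33 and 10 without pair 3, and 34 and 18 without pair 4. Within the run that held replicates 2 to 4 they were 90 and 26, and scaled to the inferred library totals 8426 and 0.

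**Figure D3:**
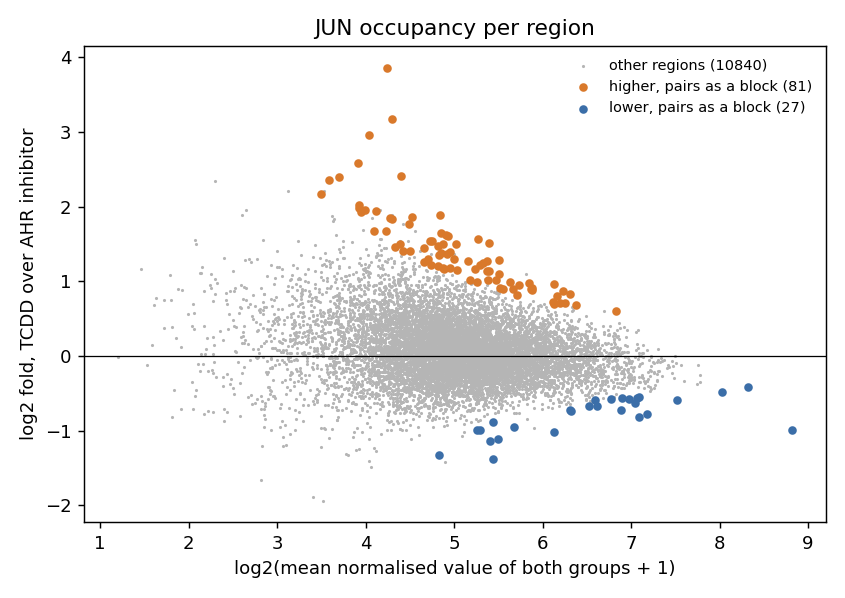
Log2 fold of each region, TCDD over AHR inhibitor, against log2 of the mean normalised signal of both groups plus 1. Coloured points are the 81 higher and 27 lower regions called by limma with the pairs as a block, and grey points the others.

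The other regions that the rule named as higher passed in limma with the block and not without it, while DESeq2 without the block also called those of GPR55, PTK2, SAMSN1, BMP2K and TSPAN33. They lay near GPR55, a G protein-coupled receptor (chromosome 2, 230974311; 19.4 ± 9.98 and 55.9 ± 10.0, SD, n = 4; log2 fold 1.57), inside PTK2, the gene of focal adhesion kinase (log2 fold 1.504), inside PREX1, an exchange factor for the GTPase RAC (0.88), inside the adaptor gene SHB (1.29), and near SAMSN1 (2.40), BMP2K (2.96, and 2.56 with blocked edgeR), TSPAN33 (1.87) and TTLL2 (1.36). A region on chromosome 14 at 98941121 with no protein-coding gene within 100 kb had a log2 fold of 1.54. Blocked limma adjusted p for these 9 regions lay between 0.0017 and 0.015. DESeq2 with the block called only 2 regions higher among all 10948, and blocked limma without the variance trend called 0.

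Regions named as lower passed in limma with the block and not without it, while DESeq2 without the block also called those of RARA, RPS25, SOX8 and FAM72D. DESeq2 with the block called only 3 regions lower among all 10948, and blocked limma without the variance trend called 0. The signal inside RARA, the gene of retinoic acid receptor alpha (chromosome 17, 40314723 to 40315123), was 92.3 ± 6.26 with the inhibitor and 45.5 ± 7.59 with TCDD (SD, n = 4; log2 fold -1.02, blocked limma adjusted p = 0.0021). A region at CASP9, which encodes an initiator caspase, went from 220.2 ± 33.7 to 146.0 ± 14.5 (SD, n = 4; log2 fold -0.58). The region at RPS25, a ribosomal protein gene, had a log2 fold of -1.33, and those at METTL25, DHRS12 and PTPRN2 had -1.12, -0.67 and -1.14. Intergenic regions 9113 bases from DIP2C and 38214 bases from SOX8 had -0.77 and -1.38. FAM72D and FAM72C (-0.81 and -0.72) are near-identical paralogs whose reads may be shared, so these are uncertain. The lowest blocked limma adjusted p of all regions, 5.5e-08, was at a lower region outside the rule, 31983 bases from NID1 and singled out after its values were seen (log2 fold -0.98, lower in 4 of 4 pairs; 0.78 without the block, since the pairs differed widely in level). The lower calls are relative to the other regions: scaled to inferred library totals, none of the 27 was called lower and their median log2 fold was 0.34.

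Among the genes fixed beforehand, CXCL13 had 1 region (chromosome 4, 77586914 to 77587314, within the gene), with 50.5 ± 16.6 and 41.0 ± 4.62 (SD, n = 4; log2 fold -0.24, lower in 3 of 4 pairs, blocked limma adjusted p = 0.70). The fold was -0.47 without inhibitor replicate 3, -0.06 without inhibitor replicate 4, -0.42 without pair 3 and -0.05 without pair 4. Scaled to inferred totals, which raises nearly all regions, it was 0.82 (limma without the block, adjusted p = 0.027). The highest region of IL22, at 68259404, held 33.95 ± 20.5 and 54.4 ± 7.98 (SD, n = 4; blocked limma adjusted p = 0.084). The highest regions of MAF, BCL6, IL21, ICOS, BATF and AHR had log2 folds of -0.30, -0.01, 0.12, -0.31, -0.03 and -0.25, and no region of these genes passed in limma on the deposited scale, with or without the block. Scaled to inferred totals, the highest regions of BCL6, BATF, AHR, IL21 and ICOS were higher without the block (adjusted p 0.0049 to 0.0441), as were 8168 of all regions, and that of MAF was not (0.53). CYP1A1, CYP1B1, PDCD1 and SOX4 had no region. The highest region of JUN had a log2 fold of 0.00 with 486.2 in TCDD replicate 1, 84.4 in inhibitor replicate 1 and 4.83 to 12.4 in the other 6 libraries.

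**Figure D4:**
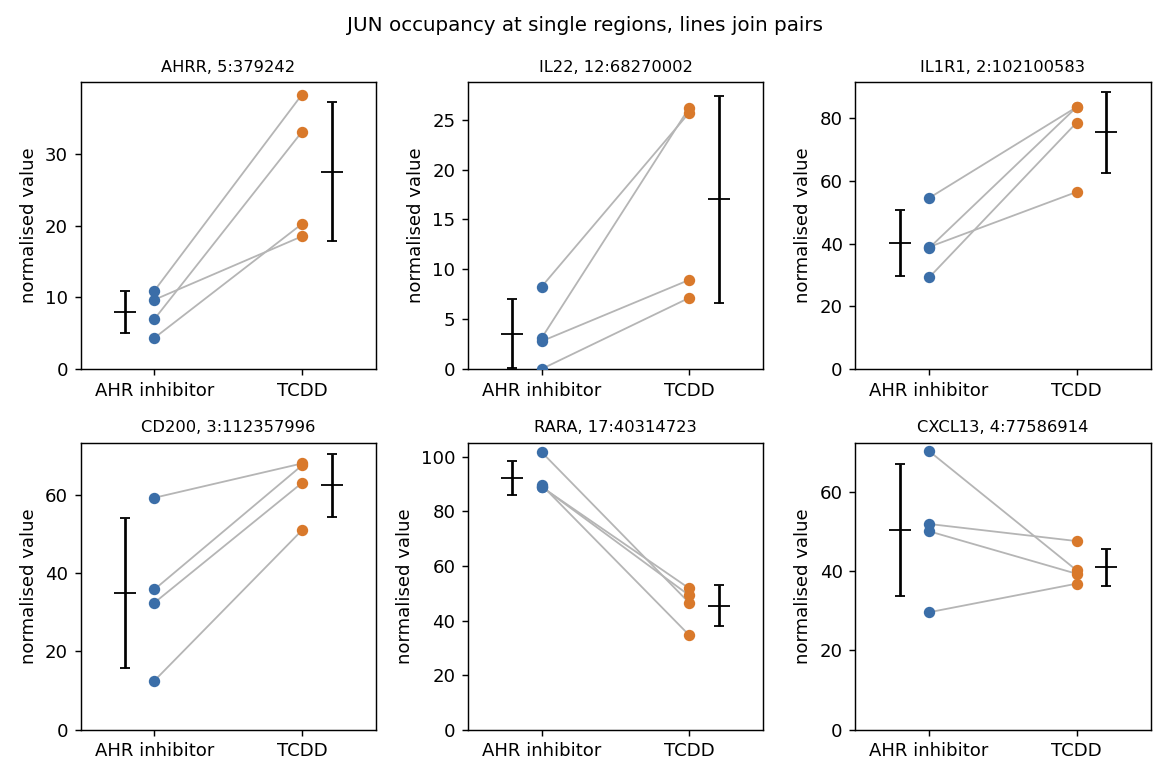
Normalised JUN signal per library at single regions of AHRR, IL22, IL1R1, CD200, RARA and CXCL13, titled by chromosome and start, with grey lines joining pairs and black marks for the mean and SD of 4 libraries. CXCL13 means were 50.5 with the inhibitor and 41.0 with TCDD, and RARA means 92.3 and 45.5.

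No gene list passed 0.05 with camera. Genes of peripheral and follicular helper T cells, the kinds that make CXCL13, had 50 regions at 15 genes, 36 fitted above 0, with a median log2 fold of 0.34 (camera adjusted p = 0.11). Their region inside CD200, a surface glycoprotein gene, held 35.03 ± 19.2 and 62.4 ± 7.95 (SD, n = 4; log2 fold 0.99, 0.58 without inhibitor replicate 2; blocked limma adjusted p = 0.027), and the one inside TIGIT had a log2 fold of 0.76 (blocked 0.14). AHR targets had 23 regions at 9 genes with a median of 0.27 (camera adjusted p = 0.11), and 2 regions, at AHRR and IL22, were higher with the block. Genes of naive and central memory T cells had 70 regions with 55 above 0 and a median of 0.20 (camera adjusted p = 0.060), and 0 passed. With an estimated correlation the camera adjusted p was 0.60 for these 3 lists and no lower for any other, and with the block it was 0.55 or more.

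Of the other lists, 3 held regions that were higher with the block, as were 81 of all 10948 regions. The Th17 and Th22, TGF-beta response and tissue residency lists had 59, 85 and 34 regions. The IL22 region below is the one also counted for AHR targets. Among genes of Th17 and Th22 cells, the median was 0.09 (camera adjusted p = 0.91), and regions at IL22 and inside IL1R1, a receptor for interleukin-1 (40.3 ± 10.5 and 75.6 ± 12.9, SD, n = 4; log2 fold 0.91), were higher with the block. In the TGF-beta response list (median 0.09, camera adjusted p = 0.27) it was a region near TGFB1 (log2 fold 0.82), and in the tissue residency list (median 0.22, camera adjusted p = 0.27) a region near RGS1, a regulator of G protein signalling (log2 fold 1.41). No region of any list was lower with the block. Medians were 0.15 for Th1, 0.16 for Th2, 0.04 for regulatory T cell, 0.01 for AP-1 family and 0.03 for T-cell activation genes (camera adjusted p 0.70, 0.91, 0.83, 0.83 and 0.91). Interferon-stimulated genes had 11 regions with a median of -0.23 (camera adjusted p = 0.37). Marker lists of other cell types had few regions: 2 for B cells (median -0.23), 2 for monocytes (0.31, both at ITGAX) and 5 for CD8 T and natural killer cells (0.29), with camera adjusted p of 0.63, 0.37 and 0.37. Adjusted over the list alone, without the block 1 region of the AHR targets and 1 of tissue residency passed and 0 in the other lists. With the block 3 higher regions passed for AHR targets, 3 for Th17 and Th22, 3 for the TGF-beta response, and 1 each for helper T cells, regulatory T cells, tissue residency and monocytes. With fry, 0 lists passed without the block. With the block the helper T cell list moved upward on balance (fry adjusted p = 0.0036), the interferon list downward (0.011) and the monocyte list upward (0.019), which rests on 2 regions of ITGAX with log2 folds of 0.52 and 0.10, the latter higher in 2 of 4 pairs. fry does not compare a list with other regions, and the interferon list's mean log2 fold was -0.08.

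**Figure D5:**
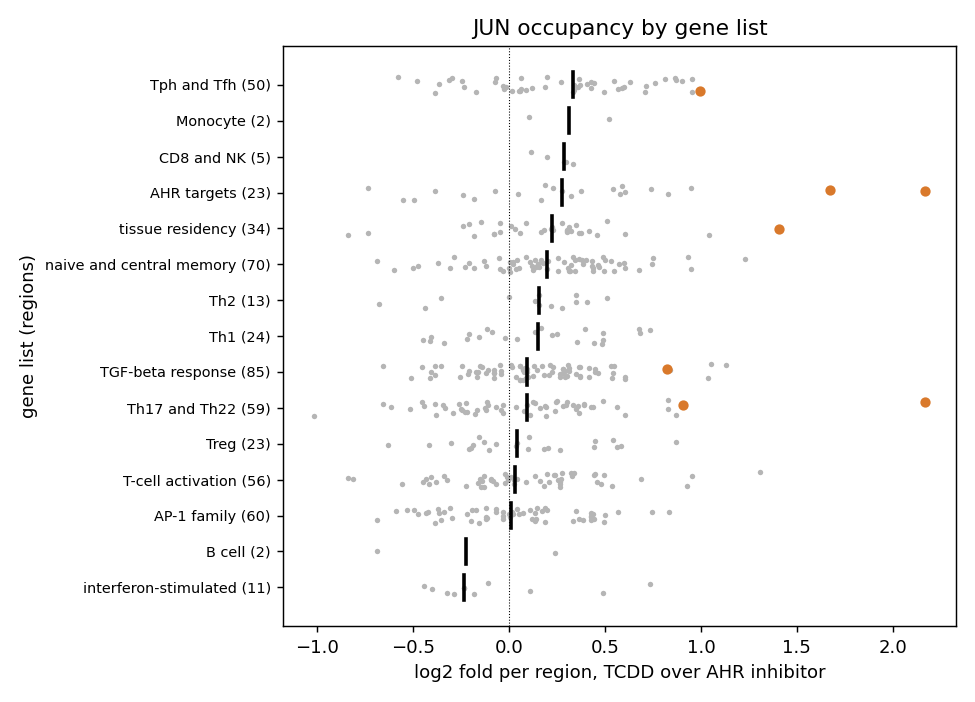
Log2 fold per region, TCDD over AHR inhibitor, for each gene list with its number of regions. Black bars are medians and orange points the regions called with the pairs as a block, of which the helper T cell list holds 1, AHR targets 2 and Th17 and Th22 genes 2.

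The change of JUN signal differed between classes of regions. Regions at gene ends had lower signal with TCDD relative to the rest (median log2 fold -0.08 over 3395 regions, camera adjusted p = 4.8e-07, 0.021 with an estimated correlation), and regions in gene bodies higher signal (median 0.12 over 4591 regions, camera adjusted p = 0.0015, 0.021 with an estimated correlation). Intergenic regions had a median of 0.09 (camera adjusted p = 0.13, 0.032 with an estimated correlation). The median at gene ends was below that of other regions in 10 of 10 equal bins of mean signal, by -0.30 to -0.13 on the log2 scale. Over all classes the median log2 fold was 0.24 in the lowest of these bins and -0.08 in the highest. Of the 81 higher regions 3 lay at gene ends, and of the 27 lower regions 12 did. The share of reads within the regions also differed between the groups, and no IgG library was used. A difference in the efficiency of the reactions and a shift of JUN binding therefore cannot be told apart for the classes.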

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

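Values in 6 of 132 groups of 4 libraries lay far from the other 3, where chance alone gives about 6.6. Of the tests in this part, those on library totals, runs, enrichment, scaling, the JUN gene, and the other groupings apart from the blocked count were chosen after the result was seen.

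At the region inside JUN (chromosome 1, 58782973), TCDD replicate 1 held 486.2 against 4.83 to 6.26 in the other TCDD libraries, and inhibitor replicate 1 held 84.4 against 7.80 to 12.4. In TCDD replicate 1 the highest point of the peak lay inside the gene (58780791 to 58784047), reached 611 fragments and was the highest of its list, 1518 bases from the nearest highest point of the other 7 libraries, which lay outside the gene with 13 to 28 fragments. A candidate explanation is DNA carrying the JUN transcript, such as a plasmid or an amplicon, whose position this distance fits. Both libraries share a run code, and whether such DNA passed between them was not tested. The 2 libraries form 1 pair, and what the code they share marks is not known, so a property of that pair stays open and was not tested.

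Single libraries stood apart at 4 other regions. RARA had 101.7 in inhibitor replicate 1 against 88.9 to 89.6, FOSB 114.7 in inhibitor replicate 1 against 79.6 to 84.1, GPR55 34.3 in inhibitor replicate 3 against 12.98 to 15.3, and ISG20 89.4 in TCDD replicate 2 against 68.4 to 70.2.

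Reads within the regions were higher in every TCDD library. The ratio of inferred library totals was 0.99, which argues against larger TCDD libraries. Both libraries of each pair share a run code, so a difference between runs could not by itself raise TCDD over inhibitor within pairs. Among replicates 2 to 4, which share a code, the lowest pair ratio of the share within the regions was 1.31. With division by inferred totals 99.6% of regions had a fold above 0. The set held 1925 regions with a peak in no inhibitor list and 187 with a peak in no TCDD list, which can favour TCDD. A difference in the efficiency of the reactions and a rise of JUN binding across the genome cannot be told apart, since no reference independent of JUN was used here, and both stay open.

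With the pairs as a block 81 regions were higher and 27 lower. The TCDD libraries held more reads. After thinning to equal reads the median absolute log2 fold of the 108 regions was 1.06 times the unthinned one, and 37 of the 108 were still called. Random thinning keeps each region's expected share of the reads. The folds were therefore bound to stay much the same, and this ratio cannot decide whether depth contributed. For the 27 lower regions the median log2 fold was 0.34 after division by inferred totals and 23 of 27 lay above 0. The same division moved the median of all regions from 0.05 to 1.09 and that of the 81 from 1.30 to 2.32. The sign of the lower regions thus depends on the scale, and this test cannot tell whether scaling caused their calls. An effect of AHR activation stays open for the regions of both directions.

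Other groupings of the 8 libraries were compared with the real one. Since the numbers pair the libraries, the real split was set against the splits that part all 4 pairs, which are 8 with the real one, too few for a share under 0.05. Without the block the real split gave 0 regions and the highest other 0, and 8 of the 8 splits reached 0, as any must. With the block 1 of the 8, the real one, reached 108, and the highest other gave 0. For peak regions called in at least 3 libraries of a group and in 0 of the other, 1 of the 8 reached the real 802, and the highest other gave 436. For gene ends and for gene bodies, 1 of the 8 gave a camera p as small as the real 1.6e-07 and 0.0010, and the smallest others were 1.0e-06 and 0.0077. For gene lists, 8 of the 8 gave at least the real 0, and the highest other gave 1. Of the other 7 splits, 4 exchange 1 pair and keep 3 as they were, so an effect of the treatment would show there too, and they include those with 436, 1.0e-06 and 0.0077. The 3 that exchange 2 pairs gave 122 to 198 peak regions and a camera p of 0.055 to 0.57 for gene ends and 0.49 to 0.71 for gene bodies. The other 27 splits keep some or all pairs whole, so they also measure differences between pairs. Among these, pairs 1 and 3 against pairs 2 and 4 gave 7 regions without the block, which points to a structure of the libraries by pair. With lists of equal length the real split gave 169 peak regions, the other 7 that part all pairs 72 to 93, and pairs 1 and 4 against pairs 2 and 3 gave 181.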

How the results depend on the processing

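Count tests, voom, thinning, inferred totals, equal list lengths and the peak height in fragments were chosen after seeing the data. The causes of the changes below were not tested unless stated. The motif sets with all their alternatives and the GC correction with and without the block were not run, since no genome sequence was used here.

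Without the block 0 regions were higher and 0 lower. With the replicate block 81 were higher and 27 lower. Other counts of higher regions without the block were 2 with pseudocount 5, 1 with quantile normalization, 2 with library weights, 2 with edgeR, 10 with DESeq2 (5 lower) and 8168 scaled to inferred library totals, which moved the median log2 fold of all regions to 1.09. The other settings without the block gave 0, and leaving out libraries or pairs gave 0 to 2 higher and 0 lower. The block changed no camera call of a list or class.

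With the pairs as a block the counts of higher and lower regions were 140 and 51 with pseudocount 5, 0 and 0 without a variance trend, 67 and 82 with limma-voom, 30 and 12 with thinned reads, 109 and 65 with edgeR, 2 and 3 with DESeq2, and 8426 and 0 scaled to inferred totals. Of the 108 regions, 108 were among those called by edgeR, 88 by limma-voom and 5 by DESeq2. Leaving out libraries or pairs gave 9 to 90 higher and 1 to 26 lower. The counts were 10 and 3 without pair 2, 10 and 1 without inhibitor replicate 2, 9 and 2 without TCDD replicate 2, 31 and 9 without inhibitor replicate 3, 15 and 7 without TCDD replicate 3, 33 and 14 without inhibitor replicate 4, and 23 and 11 without TCDD replicate 4, each fit resting on fewer libraries. Without inhibitor replicate 1 the counts were 87 and 17. In a blocked fit a library without its partner adds nothing to the folds, so leaving out 1 library leaves out its pair. The median log2 fold was 0.059 without inhibitor replicate 2, without TCDD replicate 2 and without pair 2 alike. These counts therefore do not separate effects of single libraries.

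Gene lists past 0.05 numbered 0, with 1 higher without the regions of lowest mean, 1 with quantile normalization, 1 with thinned reads (each the naive and central memory list) and 2 with 1 mean per gene (helper T cells and AHR targets). Leaving out libraries gave 0 to 2. The naive and central memory list passed without inhibitor replicate 2 (adjusted p = 0.0267), inhibitor replicate 3 (0.0480), TCDD replicate 1 (0.0175), TCDD replicate 3 (0.0382) or pair 3 (0.0236), and AHR targets without inhibitor replicate 2 (0.0267) or pair 2 (0.0442). Over libraries left out the ranges were 0.0175 to 0.580 and 0.0267 to 0.580. These calls used the preset correlation. With an estimated correlation and all libraries, the camera adjusted p was 0.60 for both lists and for helper T cells. The camera direction of lists near 0 turned, at adjusted p of 0.928 for Th2 and T-cell activation with quantile normalization, 0.997 for Th17 and Th22 with limma-voom, 0.765 for it with thinned reads, 0.787, 0.698 and 0.890 for Th17 and Th22, Th2 and T-cell activation scaled to inferred totals, 0.815 for Th17 and Th22 and T-cell activation within 10 kb, and 0.896 for T-cell activation with 1 mean per gene. With libraries left out, adjusted p ranged from 0.659 to 0.968 for Th17 and Th22, 0.550 to 0.966 for Th2, 0.390 to 0.971 for T-cell activation and 0.464 to 0.987 for regulatory T cells.

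The gene-end and gene-body classes kept their camera call and their direction relative to the other regions in all settings run. Scaled to inferred totals, 99.6% of all regions had a fold above 0, so the fall at gene ends is a relative one. The intergenic class passed with an estimated correlation (adjusted p = 0.0318) and without inhibitor replicate 1, in a range of 0.0455 to 0.477 with libraries left out.

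Peak number passed with the stricter height (ratio 2.83 in place of 1.42) and with at least 15 fragments (3.598), both at the smallest exact permutation p. In these settings the ratio for covered length went from 1.91 to 3.77 and 4.46, and that for total signal from 2.56 to 4.03 and 4.88, and these 3 measures had an adjusted p of 0.0381. With libraries left out, ratios were 1.73 to 2.25 for covered length and 2.19 to 3.28 for total signal, where so few libraries cannot reach 0.05. Peak regions called only with TCDD numbered 771, and only with the inhibitor 31. They were 1369 and 4 with the stricter height, 104 and 65 with equal list length, and 371 to 716 and 0 to 27 with pairs left out. Without pair 4 they were 371 and 27, and those only with the inhibitor were 10 without pair 1, 0 without pair 2 and 10 without pair 3.

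Of 58 named regions, 38 kept the sign of their fold in all of the up to 25 settings compared. These were the settings without the block and the planned block, while other blocked settings were not compared for sign. Most of these regions were named for a low p or for pairs that moved alike, so a kept sign was partly fixed by the selection. Scaled to inferred library totals, log2 folds turned to 0.50 at CASP9, 0.35 at FAM72C, 0.27 at FAM72D, 0.30 at DIP2C, 0.40 at DHRS12, 1.03 at BATF, 0.75 at ISG20, 0.73 at MAF, 0.0479 at RARA, 0.34 at CD22, 0.64 at FOSB, 0.75 at ICOS, 0.62 at TIPARP, 1.06 at BCL6, 0.82 at CXCL13, 0.33 at IL13 and 0.83 at AHR, since this scaling raises nearly all regions, and those of BCL6, BATF, AHR, ICOS, CXCL13 and ISG20 then passed (adjusted p 0.0049 to 0.0441). Near 0, JUN turned to -0.0361 with pseudocount 0.5, -0.0224 with median-of-ratios scaling, -0.29 with quantile normalization and -0.46 thinned. TIPARP turned to 0.0075 with library weights, 0.31 thinned, 0.0423 with edgeR and 0.0483 with DESeq2. BCL6 turned to 0.16 with quantile normalization, 0.0301 with limma-voom and 0.0045 thinned, AHR to 0.0324 with quantile normalization, and IL21 to -0.16 with edgeR and -0.23 with DESeq2. With libraries left out, log2 folds ranged from -1.57 to 0.73 at JUN, -0.25 to 0.29 at BATF, -0.0720 to 0.37 at ITGAX, -0.96 to 0.49 at MAF, -0.82 to 0.64 at TIPARP, -0.28 to 0.15 at BCL6, -0.52 to 0.55 at IL21, -0.61 to -0.04 at ICOS, -0.35 to -0.14 at AHR, -0.47 to -0.05 at CXCL13 and 0.52 to 1.18 at the highest region of IL22.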

Other observations

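The tests of neighbouring regions were set before their results were seen, and those of gene ends after.

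GPR55 and PREX1 held 3 each of the 81 regions higher with the pairs as a block, of which 1 each is among the named regions. Single regions lay near CD70 (log2 fold 1.30), DNMT3A (1.18) and inside RBPJ (2.36, and 1.99 with blocked edgeR) and NOTCH2 (0.71), the last 2 being genes of the Notch pathway, all chosen after their values were seen. The Notch pathway was not tested as a set.

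A hypothesis is that gains of JUN come in groups along the chromosome. Of the 81 regions, 16 had another of them within 100 kb, against a median of 2 and a highest value of 13 in 10000 random draws of 81 regions (permutation p = 1e-04, the smallest that these draws can give). The draws were not matched on region class, and the 4 regions between TIPARP and LEKR1 are among the 16, as are those of GPR55 and PREX1. Neighbouring regions are not independent of one another, so this p-value is too small.

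A further hypothesis is that gains avoid the ends of protein-coding genes. They held 3 of the 81 higher regions (3.70%) and 31.2% of the other regions (Fisher's exact test, two-sided p = 1.4e-09). For the lower regions it was 12 of 27, or 44.4% (Fisher's exact test, two-sided p = 0.146). Regions are not independent of one another, so these p-values are too small, and the regions were not matched on signal.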
